A study of Glycine max with 27 samples.

How the data were processed

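RNA from soybean leaves was measured on the Affymetrix soybean array, per the labels after one-cycle biotin labelling of total RNA that had been extracted with Trizol, precipitated with lithium chloride and treated with DNase. The plants were line PI200492 (cultivar Komata), which the series title ties to the rust resistance gene Rpp1. Per the labels' protocols they were sprayed with 2 ml of spore suspension (250000 spores per ml in 0.01% Tween) of Phakopsora pachyrhizi isolate HW94-1 or TW72-1, or with water and Tween. They stood in a dew chamber at 20 °C for up to 24 h and then in a greenhouse at 25 °C with 16 h days. Spores had been kept at 40 °C for 5 min, and 4 to 6 leaves were pooled per sample.

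The deposited table holds log2 values, 1 per probe set and array, which the authors made with RMA per the submitters' processing notes. The RMA version is not given in the sources used here. The labels do not say which arrays were normalized together. In the values, the largest range of array means within a sampling time was 0.028 of the range between times. Identical values were found in 13.9 to 15.0% of probe sets for pairs of mock arrays, in 0.0213 to 0.298% for pairs within a later time and in at most 0.00532% for pairs across times. The mock arrays and the arrays of each sampling time were therefore treated as separately normalized sets. Isolate contrasts lie within 1 such set. Contrasts with mock and between times cross sets, so their calls are given once as counts and are not read as tests, and levels against mock are given after quantile normalization was repeated over the 25 arrays.

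Samples were grouped by title and source name. Of 27 arrays, 2 are marked in the labels as failing quality control (replicate 1 at 24 h of each isolate) and were left out of the fits, which leaves 25 arrays in 9 groups of 3, or of 2 at 24 h. The design text says that the entire experiment had 3 biological replicates. The number of arrays limits the precision. All columns of the table belong to these samples.

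The table has 37744 probe sets. After 126 control probe sets were set aside, 37618 were tested. The platform annotation gave 1 gene for 8677 of these, several genes for 370 and none for 28571. A probe set with several genes was not named. Of the named probe sets, 8652 matched the Glycine_max_v4.0 gene table, which was used for symbols only. No gene descriptions were used here, so gene lists rest on symbols and synonyms, and 1003 genes have a symbol other than a locus number. No coordinates are given.

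Each contrast was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes) over 1 model of 9 groups without a block, with Benjamini-Hochberg adjustment over the 37618 probe sets and a threshold of 0.05. A moderated F test over the 4 isolate contrasts asked for an isolate effect at any time, and one over their 3 successive changes asked for an interaction with time. Standard errors (SE) are those of limma, and standard deviations (SD) are over arrays. Of 29 gene lists fixed beforehand, 26 had measured members. The lists for lignin, for cell cycle and histones, and for epidermis markers had none. Each list was tested with limma's camera (preset correlation 0.01) in 4 isolate and 8 mock contrasts, adjusted over all 312 tests, and again with an estimated correlation and with fry. The results of fry are not given below, and no list call rests on them. Left-out arrays and the within-time block of the list tests were adjusted over the 104 isolate tests alone. Adjusting the full tests that way gave the same counts. A list's median against mock was ranked among 10000 random lists of its size matched on mean level. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

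Genes were named by a rule. It takes the 10 largest rises and 10 largest falls per isolate contrast, and 4 and 4 per mock contrast, among called probe sets without overlap of the arrays. It adds the 6 smallest p of the interaction test, and up to 4 members with the smallest p per list described. The probe set with the highest mean stands for its gene, except that genes called with the within-time block are given by the called probe set, with their other probe sets beside it. Genes known by a locus number may be left out, which held for 51 of the 64 picks in the mock contrasts. No probe set was called in an isolate contrast, so there the names come from the lists. List members against mock were picked by p on the deposited values, so the shift between normalized sets drives some picks, such as IFR1 and CHI3A1.

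The groups, the tests, the lists, the naming rule and most alternatives were chosen before the data were examined. The alternatives were replicate number as a block, repeated quantile normalization, only the compared groups, adding the failed arrays, array weights, an intensity trend with robust prior, each array or replicate number left out, an estimated correlation and 1 probe set per gene. The planned filter on dim probe sets and a planned comparison needed probe sets with HgAffx or PsAffx IDs, of which the table holds 0, so neither was run. A filter by the 95th percentile of 21 control probe sets (IDs holding r2-Tag or r2-Ps-actin), which kept 30996 probe sets, was used after the data had been seen. The same percentile on each array, 3.84 to 5.32, also served as the background, a choice made after the results had been seen, and was carried to the scale of repeated quantile normalization for mock contrasts. A probe set above it on no array of either group is called not above background and gets no difference. Where this holds in 1 group, the difference is given as a lower bound (at least), with that group's values raised to the background, and not given where the bound is under 0. Arrays under background in the other group keep their measured values, so the bound is one of measured signal and can rest on 1 array. List medians and counts of members keep such probe sets. A block for replicate number within each sampling time was added after the model without a block and the planned block had both called 0 probe sets. The gene lists were tested with that block before they were tested without it. Left-out arrays in the list tests and splits of the arrays for the list counts were also added after list calls had been seen.

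Whether replicate numbers pair the arrays was checked by correlating, over probe sets, the deviations of same-numbered arrays of the 2 isolates from their group means. The correlations ran from 0.411 to 0.850 at 6, 12 and 48 h, each above that with any other number. At 24 h it was 0.601 for both numbers, and with 2 arrays per group the value with the other number is its mirror. With the design text's 3 replicates of the entire experiment, the numbers were taken to pair the arrays. Calls of both fits had been seen when this was written.

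The fits were tested on simulated data with 200 of 37618 probe sets changed, in 5 runs per time. Each simulated array was the mean of its real replicate pair plus independent noise with the spread found by the within-time block. The data thus follow that block by construction, so the shares do not show which fit suits the real arrays. At 48 h the model without a block recovered 21.4% of changes of 1 log2 unit and 77.0% of changes of 2, with 0 false calls. With the within-time block it recovered 67.4% and 97.6%, with 12.6 false calls on average. At 12 h the shares were 22.6% and 72.6% without the block and 69.6% and 98.8% with it, with 0 and 10.2 false calls. A list shift of 0.5 over 8677 named probe sets at 48 h was recovered in 5 of 5 runs with 0 false list calls, in simulated arrays whose genes vary independently.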

Results

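Transcripts were measured in leaves of soybean line PI200492, which carries the rust resistance gene Rpp1 per the series title, after spraying with isolate HW94-1 or TW72-1 of the rust fungus Phakopsora pachyrhizi. The sample titles call leaves sprayed with HW94-1 resistant and leaves sprayed with TW72-1 susceptible. Leaves were taken at 6, 12, 24 and 48 h, and mock-sprayed leaves at 0 h only. Each group had 3 arrays, except 2 per isolate at 24 h. The design text calls these replicates of the entire experiment, so p-values measure the spread between runs of it, and the number of arrays limits the precision. In the model without a block, that spread includes what both isolates share within a run, since same-numbered arrays deviated together. Its counts of 0 therefore do not show that the isolates had the same effect.

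Mean log2 values over the 37618 soybean probe sets differed by sampling time and hardly within a time. They were 7.27 to 7.29 in mock leaves, 6.23 to 6.24 at 6 h, 6.43 to 6.45 at 12 h, 6.64 to 6.67 at 24 h and 6.82 to 6.85 at 48 h. The isolate contrasts compare arrays within a time.

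**Figure D1:**
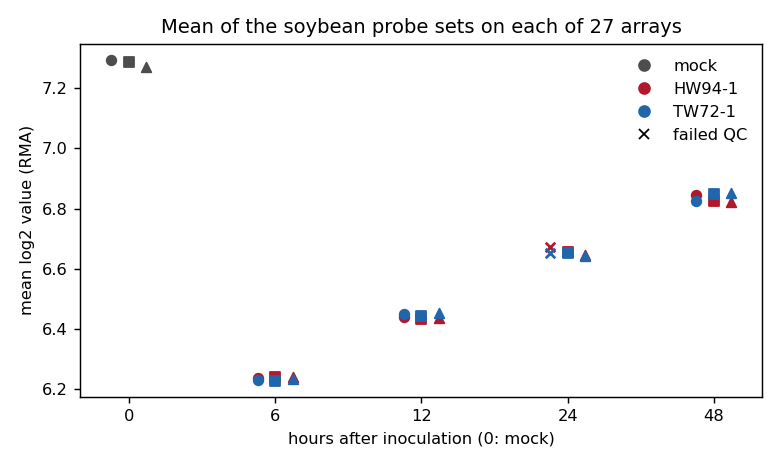
Mean log2 value over the soybean probe sets of each array (y axis) against hours after spraying (x axis, 0 for mock leaves), for HW94-1, TW72-1 and mock arrays, with crosses for the 2 arrays that failed quality control. Arrays of a sampling time lie within a narrow band, and the bands differ between times.

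The first question was how leaves with the 2 isolates differed at 48 h. Transcripts of pathogenesis-related proteins, which plants make under attack by pathogens, lay higher with HW94-1 in 15 of 15 probe sets, with a median difference of 1.17. PR-10 was at 9.29 ± 0.47 (SD, n = 3) with HW94-1 and 7.19 ± 1.64 (n = 3) with TW72-1, a difference of 2.10 (SE 0.95) seen in 2 of 3 replicate pairs. PR1-7 was at 8.44 ± 0.93 against 6.74 ± 1.22 and the osmotin-like gene OLPa differed by 1.62, each higher in 3 of 3 pairs. PR1-1 was above background on 1 of 3 arrays with HW94-1 and on 0 of 3 with TW72-1, so its bound of at least 0.03 rests on 1 array. The median of the list was 1.64, 1.83 and 0.48 in the 3 pairs. Genes of isoflavonoid synthesis, the path to the soybean phytoalexins called glyceollins, lay higher in 47 of 52 probe sets, with a median of 0.56 and pair medians of 0.79, 0.74 and 0.35. Of the 52 isoflavonoid probe sets, 43 were above background on any array of the 2 groups. CHIA1, with 1 probe set, stands in both lists. The isoflavone synthase IFS2 was at 10.67 ± 0.73 (SD, n = 3) against 8.75 ± 1.11 (n = 3), a difference of 1.92 (SE 0.86). IFR, an isoflavone reductase, was at 7.42 ± 1.30 against 5.22 ± 0.51, a difference of 2.20 (SE 0.95), while the chalcone synthase CHS8 differed by 1.69 and the chalcone reductase CHR5 by 1.65. With arrays or replicate numbers left out in turn, PR-10 ran from 1.37 (without TW72-1 replicate 1) to 3.17 (without replicate 3 of both).

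Transcription factors of the WRKY family lay higher with HW94-1 in 83 of 104 probe sets at 48 h, with a median of 0.30 that ran from 0.01 without HW94-1 replicate 3 to 0.67 without TW72-1 replicate 3. Pair medians of the WRKY list were 0.54, 0.15 and 0.16. Against all mock arrays the median of this list lay lower with both isolates at 48 h, as given further below. WRKY57 differed by 1.71 (SE 0.77, n = 3 and 3) in 3 of 3 pairs, and WRKY53 and WRKY37 differed by 1.48 and 0.74. WRKY25, above background on 2 of 3 arrays with HW94-1 and on 0 of 3 with TW72-1, was higher by at least 0.48. The circadian clock list lay lower in 8 of 8 probe sets, with a median of -0.43 and pair medians of -0.34, -0.67 and -0.51. Of its 5 genes, MYB114 was at 8.63 against 9.62, while LUXC differed by -0.48, LCL3 by -0.38 and ZTL1 by -0.09. MYB114 and LCL3 also belong to the MYB list. Cytosolic ribosomal proteins lay higher in 10 of 10 probe sets, with a median of 0.24, such as RPL37 with 0.29, RPS13 with 0.26, RPL2 with 0.15 and RPS6 with 0.14. Pair medians of the ribosome list were 0.225, 0.18 and 0.351. With arrays left out, the clock median ran from -0.66 (without TW72-1 replicate 1) to -0.34 (without HW94-1 replicate 3) and the ribosome median from 0.07 (without TW72-1 replicate 2) to 0.45 (without HW94-1 replicate 2). WRKY57 was at its lowest, 0.90, without TW72-1 replicate 2 and WRKY37, 0.41, without replicate 2 of both. MYB114 ran to -0.61 and LCL3 to 0.05 without HW94-1 replicate 2, LUXC to 0.51 without TW72-1 replicate 2, and ZTL1 to -0.01 without replicate 3 of both. RPL37 fell to 0.14 without replicate 3 of both, RPL2 to 0.08 without HW94-1 replicate 1 and RPS6 to 0.01 without TW72-1 replicate 2.

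No single probe set passed at 48 h in the model without pairs: limma called 0, with 1567 at an unadjusted p under 0.05, against 18 (14 higher and 4 lower) with the block within each time described below, and the genes named above have an adjusted p of 0.999 without pairs. Chance alone gives an unadjusted p under 0.05 in a share of 0.05 of the 37618 probe sets tested. The unadjusted count at 48 h without pairs lies under that share, as do those at 6, 12 and 24 h and of both F tests. None of these unadjusted counts is read as a sign of an isolate effect. With camera, the adjusted p was 4.25e-11 for the pathogenesis-related list, 2.23e-08 for the isoflavonoid list, 2.0e-04 for WRKY factors, 0.0161 for the clock and 0.0322 for the ribosome. With an estimated correlation none of the 5 list calls held: the adjusted p was 0.821 with an estimated correlation for the pathogenesis-related, isoflavonoid and clock lists, 0.898 for WRKY factors and 0.861 for the ribosome. Of the 10 splits of the 6 arrays into 3 and 3, 6 called at least 5 lists, and another split called 8. No member passed over all probe sets, and 0 passed adjusted over the list alone. Leaving out any array or replicate number kept the calls of the pathogenesis-related list (adjusted p 1.63e-13 to 1.06e-05) and the isoflavonoid list (5.54e-08 to 5.17e-05). The WRKY call ended without TW72-1 replicate 1 (adjusted p 0.61), HW94-1 replicate 3 (0.855) or replicate 1 of both isolates (0.367). The clock call ended without HW94-1 replicate 2 (0.0863), HW94-1 replicate 3 (0.0844), TW72-1 replicate 3 (0.0887) or replicate 3 of both (0.0992), and with 1 probe set per gene (0.162). The ribosome call ended without HW94-1 replicate 1 (0.535) or 3 (0.23), TW72-1 replicate 2 (0.583) or 3 (0.12), replicate 2 (0.0627) or 3 (0.2) of both, and with 1 probe set per gene (0.21). The poly-A spike controls lay lower with HW94-1 in 3 of 3 pairs at 48 h, with a mean difference of -1.46.

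**Figure D2:**
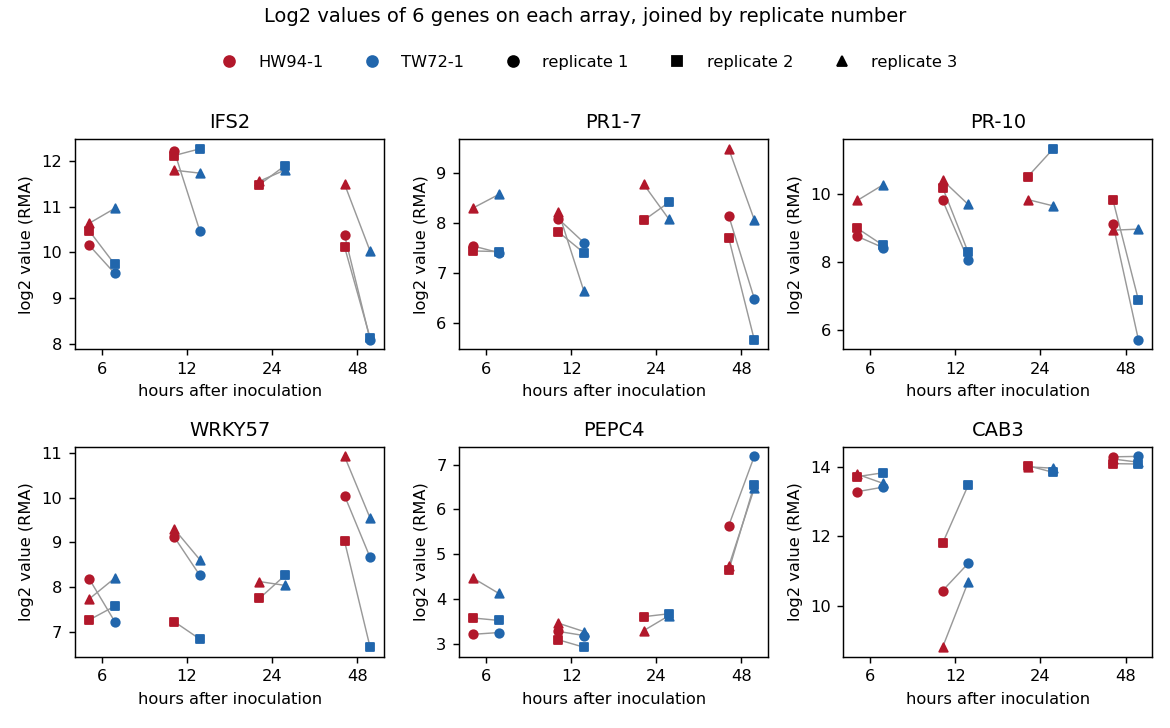
Log2 values per array (y axis) of IFS2, PR1-7, PR-10, WRKY57, PEPC4 and CAB3 against hours after spraying (x axis), in red for HW94-1 and blue for TW72-1, with circles, squares and triangles for replicates 1, 2 and 3 and grey lines joining arrays of the same number. For PEPC4 the probe set called with the block within each time is drawn. The genes were chosen after their values were seen, and at 48 h the HW94-1 array lies above its TW72-1 partner in 3 of 3 pairs for IFS2, PR1-7 and WRKY57 and in 2 of 3 for PR-10.

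At 12 h the pathogenesis-related list lay higher with HW94-1 in 14 of 15 probe sets, with a median of 0.74 and pair medians of 0.74, 0.50 and 0.61. PR-10 was at 10.13 ± 0.30 (SD, n = 3) against 8.68 ± 0.88 (n = 3), a difference of 1.45 (SE 0.94), OLPa at 7.76 ± 0.64 against 6.31 ± 0.88, and PR1-7 differed by 0.83. PR1-1 was above background on 1 of 3 arrays with HW94-1 and on 0 of 3 with TW72-1, so no difference is given. The list had pair medians of 0.38, 0.20 and -0.01 at 6 h and of -0.44 and 0.19 at 24 h, where it was not called. Photosynthesis genes lay lower in 12 of 16 probe sets, with a median of -0.31 and pair medians of 0.09, -0.53 and -0.41. CAB3, a chlorophyll a/b-binding protein, was at 10.35 ± 1.51 (SD, n = 3) against 11.79 ± 1.48 (n = 3), a difference of -1.45 (SE 0.58) with the lower value under HW94-1 in 3 of 3 pairs. The photosystem gene PSAD differed by -0.20, and of the rubisco activases RCA14 differed by -0.46 and RCABETA by 0.75. Isoflavonoid genes lay higher in 43 of 52 probe sets, with a median of 0.26, such as CYP93A2 with 0.93, the prenyltransferase G4DT with 0.85, CHI1B1 with 0.75 and CYP93A1 with 0.52. The pair medians of this list were 1.36, -0.15 and -0.08, and 41 of its 52 probe sets were above background on any of the 6 arrays. When arrays were left out, the photosynthesis median ran from -0.51 (without replicate 1 of both) to -0.15 (without TW72-1 replicate 2) and the isoflavonoid median from -0.08 (without replicate 1 of both) to 0.73 (without TW72-1 replicate 2). Without TW72-1 replicate 1 G4DT was at 0.03 and CYP93A1 at -0.13. CAB3 was at -0.61, RCABETA at 0.29 and CYP93A2 at 0.53 without TW72-1 replicate 2, RCA14 at -0.16 and PSAD at -0.09 without HW94-1 replicate 3, CHI1B1 at 0.32 without HW94-1 replicate 2 and PR1-7 at 0.45 without replicate 3 of both.

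At 12 h 5 more lists were called, and none of these calls held with an estimated correlation (adjusted p 0.821 to 0.861). Peroxidases lay higher in 5 of 7 probe sets, with a median of 0.16. PRX4 differed by 1.41 (SE 0.67, n = 3 and 3) in 3 of 3 pairs, PRX3 differed by 0.16, PRX2B by 0.07 and PRX2 by -0.56. Cell wall genes lay lower in 10 of 12 probe sets, with a median of -0.36, among them the expansin EXP2 with -1.11 and the proline-rich protein PRP2 with -0.73, while EXP1 and PRP1 were not above background. Lipoxygenase and jasmonate genes lay lower in 24 of 34 probe sets, with a median of -0.16, such as the vegetative storage protein VSPA with -1.81 and the allene oxide synthase AOS2 with -0.36, while LOX1.1 and LOX2 were not above background. The list named abscisic acid and water stress lay lower in 23 of 30 probe sets, with a median of -0.14, among them the aquaporins PIP1-8 with -0.35, PIP1-10 with -0.27 and PIP1-7 with -0.14, while LEA5 was not above background. Apart from ERD15, LEA-2, LEA5 and MAT1, its 18 genes are all aquaporins, so abscisic acid is only the name of the list here. Root or nodule markers lay lower in 14 of 17 probe sets, with a median of -0.13, but 4 of the 17 were above background on any of the 6 arrays. N-26B and N-56 were not, and ENOD55-2 was on 1 array. Left-out arrays gave medians from 0.09 (without TW72-1 replicate 3) to 0.59 (without HW94-1 replicate 3) for peroxidases, and the highest medians of the other lists were cell wall -0.12 and abscisic acid 0.03 without HW94-1 replicate 3, lipoxygenases -0.01 without TW72-1 replicate 3, and root or nodule markers -0.07 without TW72-1 replicate 2. Without HW94-1 replicate 3 VSPA was at -0.45, AOS2 at -0.18, PIP1-10 at -0.13, PIP1-7 at 0.03 and PRX2 at 0.59. PRX4 was at 0.87 without HW94-1 replicate 2, EXP2 at -0.58 and PRX2B at -0.08 without HW94-1 replicate 1, PIP1-8 at -0.06 without TW72-1 replicate 2, PRP2 at -0.30 without replicate 2 of both and PRX3 at -0.01 without replicate 3 of both.

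Again limma called 0 probe sets at 12 h in the model without pairs, with 508 at an unadjusted p under 0.05 and an adjusted p of 1 for the genes named, against 5 (4 higher and 1 lower) with the block within each time. The adjusted p with camera was 1.3e-06 for the pathogenesis-related list, 1.61e-06 for photosynthesis, 7.2e-04 for isoflavonoids, 0.00326 for peroxidases, 0.0161 for root or nodule markers, 0.0239 for abscisic acid, 0.0258 for lipoxygenases and 0.0322 for the cell wall. None of these 8 calls held with an estimated correlation: the adjusted p was 0.821 with an estimated correlation for the pathogenesis-related, photosynthesis, peroxidase, root or nodule and abscisic acid lists, 0.855 for isoflavonoids, 0.861 for lipoxygenases and 0.834 for the cell wall. Of the 10 splits of the 6 arrays, the real one called the most lists, and the highest other called 7. Adjusted over the list alone, 1 peroxidase and 1 MYB probe set passed, and 0 of either passed over all probe sets. The poly-A spike controls lay higher with HW94-1 in 3 of 3 pairs at 12 h, with a mean difference of 0.71.

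The pathogenesis-related call at 12 h held without each array or replicate number (adjusted p 6.52e-07 to 0.00235). The photosynthesis call ended without HW94-1 replicate 3 (0.152) and with 1 probe set per gene (0.104). The isoflavonoid call ended without HW94-1 replicate 1 (0.0601), TW72-1 replicate 1 (0.916) or HW94-1 replicate 2 (0.174), and its median was -0.08 without replicate 1 of both isolates (0.882). The peroxidase call ended without HW94-1 replicate 2 (0.323), without replicate 2 of both (0.137), with 1 probe set per gene (0.28) and with a block for replicate number within each time (0.181). The cell wall call ended without HW94-1 replicate 1 (0.0573), 2 (0.056) or 3 (0.452), TW72-1 replicate 1 (0.0986) or 2 (0.224), or replicate 2 (0.182) or 3 (0.154) of both, and was at 0.0552 with replicate number as a block. The lipoxygenase call ended without HW94-1 replicate 1 (0.839) or 3 (0.106), TW72-1 replicate 2 (0.125) or 3 (0.831), or replicate 1 (0.0745) or 3 (0.812) of both. The abscisic acid call ended without TW72-1 replicate 1 (0.159) or 2 (0.233), or replicate 1 (0.122) or 3 (0.353) of both, and its median was 0.03 without HW94-1 replicate 3 (0.906). The root or nodule call ended without HW94-1 replicate 1 (0.409), TW72-1 replicate 2 (0.103) or 3 (0.319), replicate 1 (0.0672) or 3 (0.256) of both, and with the block within each time (0.0545).

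**Figure D3:**
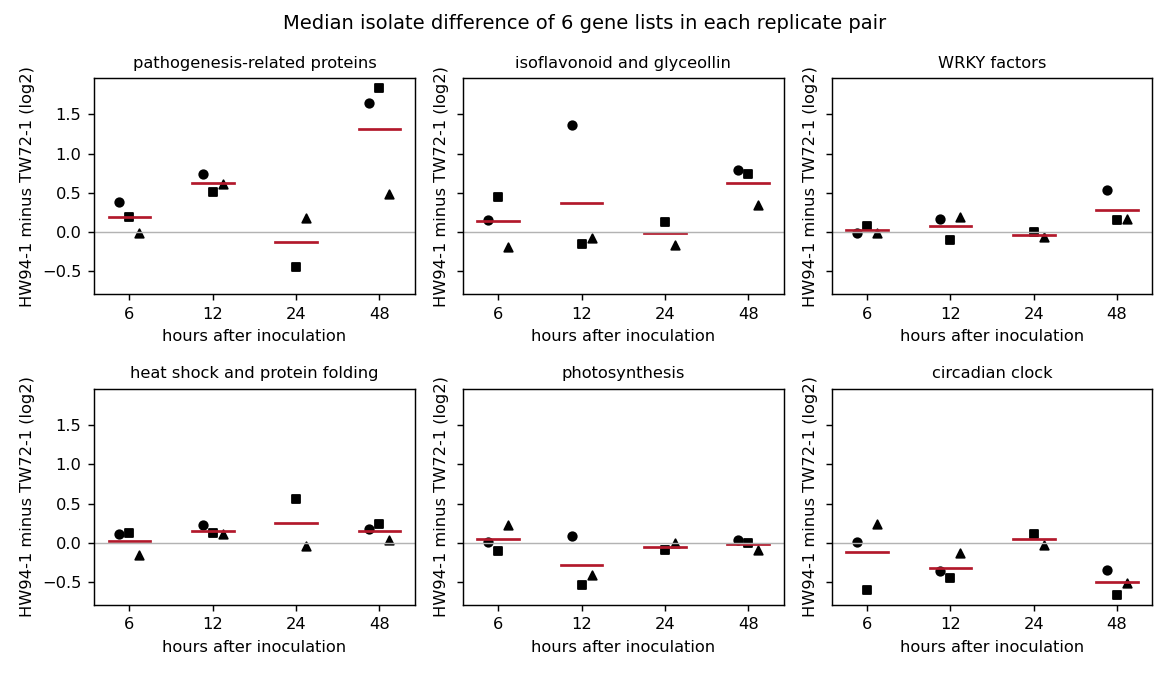
Median difference, HW94-1 minus TW72-1, over the probe sets of 6 gene lists (y axis, log2) in each replicate pair (points) at 6, 12, 24 and 48 h (x axis), with a red bar for the mean of the pairs. The pathogenesis-related list lies above 0 in 3 of 3 pairs at 12 h and at 48 h, in 2 of 3 at 6 h and in 1 of 2 at 24 h.

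At 6 h phloem and vascular markers lay higher with HW94-1 in 12 of 14 probe sets, with a median of 0.30, but 9 of the 14 were above background on any of the 6 arrays. The sieve element gene SEO-F3 differed by 0.34 and SEOA, above background on 2 of 3 arrays of each isolate, by 0.57. SEOM was not above background, and the sucrose transporter SUT1 was at 6.43 ± 1.27 (SD, n = 3) against 6.02 ± 1.04 (n = 3). Isoflavonoid genes lay higher in 40 of 52 probe sets, with a median of 0.15, and included IFR2 with 0.51, CHR5 with 0.48 and CHI1A with 0.45, while CHI3A1 was not above background. Of the 52, also 40 were above background on any of the 6 arrays, which need not be the same probe sets. Root or nodule markers lay higher in 12 of 17 probe sets, with a median of 0.06, but 3 of the 17 were above background on any of the 6 arrays, and the nodulins N-26B, N-44, N-23 and N-26 were not. At 24 h, with 2 arrays per isolate, genes of heat shock and protein folding lay higher in 32 of 43 probe sets, with a median of 0.25 and pair medians of 0.56 and -0.05. The heat shock factor HSF-26 differed by 0.61 and HSF-08, above background on 2 of 2 arrays against 1 of 2, by 0.46. HSF-35 was above background on 1 of 2 arrays with HW94-1 and on 0 of 2 with TW72-1. Its bound of at least 0.12 rests on that 1 array, and the difference was -0.02 without HW94-1 replicate 2. HSF-35 is therefore not read as different between the isolates. The disulfide isomerase PDIQ-1A differed by -0.29. The list of darkness and sugar starvation, which holds only 2 genes, lay lower in 5 of 5 probe sets, with a median of -0.51. The amylase BMY2 was at 11.86 ± 0.13 (SD, n = 2) against 12.37 ± 0.14 (n = 2), and the asparagine synthetase AS2 differed by -0.35. With arrays left out, the phloem median was lowest, 0.08, without HW94-1 replicate 2, and that of root or nodule markers at 6 h ran from 0.01 (without replicate 1 of both) to 0.18 (without HW94-1 replicate 3). The isoflavonoid median at 6 h ran from -0.01 (without replicate 2 of both) to 0.39 (without TW72-1 replicate 3). SEO-F3 and SEOA were at 0.00 and 0.04 without replicate 1 of both, SUT1 at -0.19 and CHI1A at 0.15 without TW72-1 replicate 1, CHR5 at 0.10 without replicate 2 of both and IFR2 at -0.17 without HW94-1 replicate 3. At 24 h the heat shock median was 0.56 and the starvation median -0.70 without replicate 3 of both, and they were -0.05 and -0.32 without replicate 2 of both. Without TW72-1 replicate 2 HSF-26 was at 0.06, HSF-08 at -0.30 and PDIQ-1A at 0.11, and BMY2 was at -0.32 without replicate 2 of both and AS2 at 0.36 without replicate 3 of both.

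limma called 0 probe sets at 6 h and 0 at 24 h, with 160 and 472 at an unadjusted p under 0.05 and an adjusted p of 1 for the genes named. At 6 h the adjusted p with camera was 4.03e-04 for phloem markers, 0.00257 for isoflavonoids and 0.00349 for root or nodule markers, against an adjusted p of 0.821, 0.861 and 0.821 with an estimated correlation. At 24 h it was 0.00127 for heat shock and 0.0188 for starvation, against an adjusted p of 0.855 and 0.821 with an estimated correlation. Adjusted over the list alone, 1 heat shock probe set passed at 24 h and 0 at 6 h. Without HW94-1 replicate 3, limma called HSF-35 at 24 h, from 1 array against 2 that were not above background. Of the 10 splits at 6 h, 8 called at least 3 lists. The poly-A spike controls lay lower with HW94-1 in every pair, with mean differences of -0.91 at 6 h and -0.60 at 24 h. Hybridization controls also lay lower in every pair, with mean differences of -0.41 at 6 h and -0.60 at 24 h, and rRNA probe sets in 2 of 2 pairs at 24 h, with -0.34. The 3' minus 5' difference of ubiquitin at 24 h was higher with HW94-1 in 2 of 2 pairs, by 0.63 in replicate 2, where the heat shock list lay higher, and by 0.07 in replicate 3, and that of actin in 1 of 2.

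The phloem call ended without TW72-1 replicate 1 (0.0806), HW94-1 replicate 2 (0.171) or replicate 1 of both (0.141). The isoflavonoid call at 6 h ended without TW72-1 replicate 1 (0.922) or 2 (0.116), HW94-1 replicate 2 (0.327) or 3 (0.211) and with 1 probe set per gene (0.0703), and its median was -0.01 without replicate 2 of both (0.483). The root or nodule call at 6 h ended without HW94-1 replicate 1 (0.229) or 2 (0.327), TW72-1 replicate 1 (0.079), or replicate 1 (0.539) or 2 (0.192) of both, and its median was -0.05 with dim probe sets left out (0.971). The heat shock call ended without HW94-1 replicate 2 (0.125) or TW72-1 replicate 2 (0.505) and with 1 probe set per gene (0.1), and its median was -0.05 without replicate 2 of both (0.862). The starvation call ended without HW94-1 replicate 2 (0.195) or 3 (0.0766), TW72-1 replicate 2 (0.105) or 3 (0.288), or replicate 3 of both (0.333), and also without replicate 1 at the other times (0.0554).

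Over the 4 times, 12 lists had no isolate call: MYB and NAC factors, calcium signalling, ethylene, flavonols and anthocyanins, glutathione and antioxidants, guard cell markers, phenylpropanoid entry, proteinase inhibitors, receptor-like kinases, resistance-like proteins, and salicylate and systemic resistance. Their adjusted p ran from 0.0663 to 0.985. Guard cell markers were probe sets of MYB60 alone, and RPS6 and RPS13 stand in both the resistance-like and the ribosome list. The F test of an isolate effect at any time called 0 probe sets (356 at an unadjusted p under 0.05), and the interaction with time called 0 (334). Left-out arrays changed these counts: without TW72-1 24 h replicate 3 they were 12 and 10, and without HW94-1 24 h replicate 2, TW72-1 48 h replicate 2 or HW94-1 48 h replicate 3 each was 1, as was the interaction without HW94-1 24 h replicate 3. The 6 genes with the smallest p of the interaction are known by locus numbers, and each has an adjusted p of 1.

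The replicate numbers paired the arrays. Replicate number as a block called 0 at each time and in both F tests, with 238, 890, 786 and 2443 probe sets at an unadjusted p under 0.05 at 6, 12, 24 and 48 h. A block within each time, added after these counts of 0, called 0, 5, 0 and 18 probe sets at 6, 12, 24 and 48 h, with 698, 2661, 2202 and 5674 at an unadjusted p under 0.05. The share of 0.05 that chance alone gives was exceeded at 12, 24 and 48 h with this block and at 48 h alone with the additive block. Probe sets are not independent, so this excess is not read as a test. Of the 4 ways to swap isolates within pairs, the real one called the most, and the highest other called 0 at 12 h and 1 at 48 h. With an intensity trend it called 10 and 101 at 12 and 48 h, with a robust prior too 10 and 102, and with each time fitted alone 0. Repeated quantile normalization with the additive block called 0. In the block within each time, 1 of 2 probe sets of PEPC4, a phosphoenolpyruvate carboxylase, was lower with HW94-1 than with TW72-1 at 48 h. Its difference was -1.73 (SE 0.12, adjusted p 5.76e-04), at 5.00 ± 0.55 (SD, n = 3) against 6.73 ± 0.39 (n = 3). The other PEPC4 probe set, which has the higher mean, was not called (adjusted p 0.217), with pair differences of -0.54, -2.94 and -0.40. A pair of probe sets of LOC100809397 lay higher with HW94-1 by 2.79 and 2.25 at 48 h (adjusted p 5.76e-04 and 0.00194) and by 2.13 and 1.61 at 12 h (0.0169 and 0.0297). The first was above background on 2 of 3 TW72-1 arrays at both times and the second on 1 of 3 at 12 h. The called probe set of PEPC4 was above background on 2 of 3 HW94-1 arrays at 48 h, and that of LOC100499938 on 2 of 3 TW72-1 arrays. In 1 of its 3 probe sets LOC100499938 lay higher with HW94-1 by 1.86 (0.0444) at 48 h, with 1.25 (0.0546) and 0.22 (0.64) in the others. Pair differences were 2.22, 2.44 and 0.94 in the called one. In 1 of its 4 probe sets LOC732598 lay lower with HW94-1 by 1.41 (0.0437) at 48 h, with -0.29 (0.545), -0.50 (0.479) and -0.46 (0.541) in the others. Pair differences were -0.76, -1.69 and -1.77 in the called one. With single arrays left out of the model without a block, LOC732598 ran from -2.58 (without HW94-1 replicate 1) to -0.26 (without HW94-1 replicate 3) and LOC100499938 from 0.95 (without TW72-1 replicate 1) to 2.60 (without HW94-1 replicate 1). Of the called probe sets, 13 of the 18 at 48 h and 3 of the 5 at 12 h had no gene. Left-out pairs moved these counts: 43, 0 and 1 calls at 12 h without replicate 1, 2 or 3, 6 and 1337 at 24 h without replicate 2 or 3, and 10, 5 and 55 at 48 h without replicate 1, 2 or 3. In the model without a block, the count at 24 h was 118 without TW72-1 replicate 3, 31 without replicate 3 of both, 3 without HW94-1 replicate 3, 2 without TW72-1 replicate 2 and 1 without HW94-1 replicate 2. It was 1 at 12 h without HW94-1 replicate 1, and at 48 h 2 without HW94-1 replicate 3 and 1 without HW94-1 replicate 1, TW72-1 replicate 2 or replicate 3 of both.

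Levels against mock leaves were set side by side after repeated quantile normalization, without a test. The 3 mock arrays lay far apart in some defence genes: IFS2 was at 11.64, 6.02 and 9.07 in replicates 1, 2 and 3, where the group means of inoculated leaves ran from 8.55 to 12.22, and PR1-7 at 10.09, 5.78 and 7.33, where they ran from 6.53 to 8.32. Both genes were chosen after their values were seen. Isoflavonoid genes had median differences from mock of 1.17, 1.64, 1.36 and 0.83 for HW94-1 and 0.78, 1.26, 1.34 and 0.23 for TW72-1 at 6, 12, 24 and 48 h. Each was at the 100th percentile of 10000 random lists except that of TW72-1 at 48 h, at 91.8, where 5 of 52 probe sets lay at least 1 log2 unit above mock without overlap. These percentiles set a list against other genes and carry no spread between arrays. Without mock replicate 2 the medians were 0.75, 1.47, 1.03 and 0.57 for HW94-1 and 0.51, 1.05, 1.16 and 0.08 for TW72-1, and without mock replicate 1 that of TW72-1 at 48 h was 0.61. CYP93A3, above background on 1 of 3 mock arrays, was at 4.33 ± 1.14 (SD, n = 3) in mock leaves and at 9.47 ± 0.52 (n = 3) and 9.28 ± 0.35 (n = 3) with HW94-1 and TW72-1 at 6 h. The dehydratase HIDH, which makes isoflavones, differed from mock by 2.82 and 2.88 at 6 h, and CHS1 by 3.81 and 3.35 at 24 h. Pathogenesis-related genes had median differences from mock of 0.49, 1.46, 0.81 and 1.64 with HW94-1 and 0.64, 0.95, 1.08 and 0.49 with TW72-1, at percentiles of 98.2 to 100 with HW94-1 and of 94.7 to 100 with TW72-1. Of the 15 probe sets, 4, 7, 6 and 5 with HW94-1 and 3, 2, 6 and 0 with TW72-1 lay at least 1 log2 unit above mock without overlap. The direction depended on mock replicate 2: without it the medians were -0.22, 1.08, 0.37 and 0.77 with HW94-1 and -0.02, 0.33, 0.66 and -0.23 with TW72-1. Without mock replicate 1 they were 1.60, 2.06, 2.16 and 2.22 and 1.37, 1.41, 1.91 and 1.09, and without mock replicate 3 those at 6 h with HW94-1 and at 48 h with TW72-1 were 0.28 and 0.04. PR-10, at 6.38 ± 2.59 (SD, n = 3) in mock leaves and above background on 2 of these 3 arrays, differed by 3.88 and 2.41 at 12 h. The peroxidase PRX4 was not above background in mock leaves, and lay higher by at least 5.68 and 4.24 at 12 h, by at least 5.93 and 5.12 at 24 h and, with HW94-1, by at least 1.34 at 48 h.

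Photosynthesis genes had medians of -1.04 with HW94-1 and -0.80 with TW72-1 at 12 h (percentile 0 each), and 0.01 and 0.04 at 48 h (55.4 and 62.6). RCA14 was at 13.10 ± 0.07 (SD, n = 3) in mock leaves and differed by -1.39 and -0.98 at 12 h. The clock list had medians of -1.36 and -1.16 at 12 h (percentiles 0.17 and 0.14), with LHY at -3.23 and -2.32, LCL3 at -3.12 and -3.19, and MYB114 at -5.70 and -5.06 against mock, above background at 12 h on 1 and 2 of 3 arrays. AS2 was at 11.77 ± 0.78 (SD, n = 3) in mock leaves, 4.68 ± 0.45 (n = 3) with HW94-1 and 5.40 ± 1.26 (n = 3) with TW72-1 at 12 h, above background on 2 of 3 arrays of each isolate. Heat shock and folding genes lay above mock by 1.24 and 1.30 at 48 h (percentile 100 each), and at 24 h HSP90A1 differed by 4.26 and 3.62. NAC factors lay below mock by medians of -1.41 and -1.46 at 48 h (percentile 0 each), with NAC1, above background on 2 of 3 arrays of each isolate, at -5.20 and -5.23 and NAC12 at -4.15 and -4.57, and without mock replicate 3 the median with TW72-1 was -0.95. WRKY factors lay below mock by medians of -0.19 with HW94-1 and -0.56 with TW72-1 at 48 h (percentile 0 each). Without mock replicate 3 the WRKY median with HW94-1 was 0.065. WRKY57 was at 10.60, 7.60 and 9.94 in mock replicates 1, 2 and 3, and at a mean of 9.84 with HW94-1 at 48 h. The ribosome list had medians of 1.18 and 0.93 at 48 h (percentiles 99.97 and 99.91), with RPS13 at 1.39 and 1.14. Mock leaves were taken at 0 h only, so hours, light, dew chamber and inoculation differ together.

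At 6, 12, 24 and 48 h, 2552, 2523, 3437 and 3100 probe sets lay at least 1 log2 unit above mock without overlap of the arrays with HW94-1, and 2747, 2521, 3316 and 3327 lay that far below. With TW72-1, 2844, 2333, 2417 and 2906 lay above and 3081, 2480, 2474 and 2981 below. Chance gives no overlap in 10% of probe sets for 3 against 3 arrays and 20% for 2 against 3; the shares found were 40.5, 37.5, 51.2 and 40.9% with HW94-1 and 44.3, 39.6, 44.5 and 40.7% with TW72-1. In the deposited values, the median probe set lay -0.98, -0.81, -0.59 and -0.39 from mock with HW94-1 and -0.99, -0.80, -0.60 and -0.38 with TW72-1, and after repeated quantile normalization 0.01 to 0.03. limma on the deposited values called 500 probe sets higher and 27460 lower at 6 h with HW94-1, 933 and 22829 at 12 h, 1351 and 16686 at 24 h, and 2230 and 13235 at 48 h. After repeated quantile normalization it called 4089 and 3536, 4533 and 3605, 4330 and 3517, and 5509 and 5233. With TW72-1 the deposited values gave 600 and 27323, 793 and 22783, 753 and 16052, and 1937 and 12899, against 4627 and 3956, 3948 and 3075, 2863 and 2250, and 4953 and 4876. These counts cross separately normalized sets and are not read as tests.

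The same holds between successive times. In the deposited values limma called 4762 probe sets higher and 1783 lower from 6 to 12 h with HW94-1, 5712 and 1435 from 12 to 24 h, and 9712 and 4610 from 24 to 48 h. With TW72-1 the counts were 3830 and 1008, 3650 and 771, and 8900 and 4276. After repeated quantile normalization they were 1380 and 1631, 2502 and 1961, and 5015 and 5448 with HW94-1, and 923 and 1129, 1247 and 977, and 5165 and 5463 with TW72-1.

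Differences from mock were set against each other across genes, which are not independent replicates. In the deposited values the correlation between isolates was 0.98, 0.957, 0.948 and 0.935 at 6, 12, 24 and 48 h. After repeated quantile normalization it was 0.978, 0.959, 0.949 and 0.936. For the deposited values, unchanged groups against the same mock arrays gave 0.507, 0.516, 0.394 and 0.491 in simulation with the isolates drawn independently. With same-numbered arrays correlated as found, added after these values were seen, they gave 0.777, 0.834, 0.759 and 0.859. The covariance in the deposited values was 0.768, 0.731, 0.766 and 0.834 against a simulated 0.0784, 0.0792, 0.0743 and 0.0729, or 0.121, 0.129, 0.143 and 0.128 with that pairing. After repeated quantile normalization, 3625, 3417, 2568 and 4053 probe sets were called higher with both isolates, where independent lists give 503, 476, 330 and 725, and 3157, 2730, 2024 and 4030 lower, where they give 372, 295, 210.4 and 678. In the deposited values 470, 675, 660 and 1496 were called higher with both, where independent lists give 7.98, 19.7, 27.0 and 115, and 26458, 21349, 14421 and 11046 lower, where they give 19940, 13830, 7120 and 4538. With 3 mock arrays no split of them leaves 2 on each side, so part of the excess over independent lists may come from the shared mock arrays, and part from the pairing of the isolates' arrays. Both isolates of a time also shared hours, light and dew chamber, and were set against mock across separately normalized sets. The simulations hold none of this. Counts in the deposited values also carry the shift of the median probe set below mock given above.

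The 2 arrays that failed quality control, replicate 1 of both isolates at 24 h, correlated across probe sets at 0.988 with each other and at 0.916 to 0.974 with the other 4 arrays of 24 h, which correlated at 0.941 to 0.992 among themselves. Their hybridization controls were at 10.1 and 11.7, against 7.99 to 8.96 in those 4 arrays. In another normalized set, an array not marked as failing (HW94-1 12 h replicate 1) was at 10.4, above the lower of these values. Fungal transcripts were not analysed here.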

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

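The tests of separate normalization, of a single pair, of spike controls and of RNA degradation, and the block for replicate number within each sampling time, were chosen after the results they bear on had been seen, and so were the splits for the counts of 0 and the splits and swaps for called lists.

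The called PEPC4 probe set passed the test of an isolate difference that changes between times, in the block within each sampling time (adjusted p of the interaction 0.0424, limma), and its difference was -1.73 at 48 h. At 12 and 24 h no array of either isolate was above background for it, and at 6 h 1 of 6 was. The differences at those times are therefore not given, and the test does not show that an isolate difference of PEPC4 changed with time. That of LOC100809397 also passed (0.0432), with 2.13, 0.39 and 2.79 at 12, 24 and 48 h, while at 6 h it was above background on 0 of 3 HW94-1 and 1 of 3 TW72-1 arrays. Without that block the interaction test called 0 probe sets, so neither gene passed it.

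The pathogenesis-related and isoflavonoid lists lay higher with HW94-1 at 48 h, with medians of 1.17 and 0.56. A single pair is argued against, since both lists lay higher in 3 of 3 pairs. A fixed effect of RNA amount on the pathogenesis-related list is argued against by the spike controls, whose difference was -1.46 at 48 h and 0.71 at 12 h, each with the same sign in 3 of 3 pairs, while that list lay higher in 3 of 3 pairs at both times. For the isoflavonoid list a fixed effect stays open, since that list lay higher in 1 of 3 pairs at 12 h. An effect of RNA amount at 48 h alone stays open for both lists, since the spike controls at 12 h do not bear on it. RNA degradation stays open, since the 3' minus 5' differences of actin and of ubiquitin were each higher with HW94-1 in 2 of 3 pairs and lower in 1. The isolate, which the design names, stays open too and may account for the lists as a hypothesis. Of the 10 splits of these 6 arrays, 6 called at least as many lists as the real 5. These splits break the pairs, so they cannot tell the isolate from differences between replicates. For both lists the real grouping alone gave a camera p as small, in 1 of 10 splits and 1 of 4 swaps within pairs. That is too few for a share under 0.05, and another swap called 6 lists.

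At 12 h the photosynthesis list lay lower and the pathogenesis-related list higher with HW94-1, with medians of -0.31 and 0.74. A single pair stays open for the photosynthesis list, which lay lower in 2 of 3 pairs, and without HW94-1 replicate 3 its adjusted p was 0.152. RNA degradation stays open, since the 3' minus 5' difference of actin was higher with HW94-1 in 1 of 3 pairs and that of ubiquitin in 2 of 3. The isolate stays open as a biological explanation.

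In the deposited values most probe sets lay lower in inoculated than in mock leaves. Separate normalization of the sampling times is a candidate explanation: the largest range of array means within a time was 0.028 of the range between times. A change in the total RNA of the leaves was not tested, and mock leaves at 0 h leave no biological explanation that could be set apart from time.

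Other splits of the arrays were counted for each result with 3 arrays per group. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The isolate counts were 0 at 6, 12 and 48 h, which all 10 splits meet by construction, and the highest other splits called 0, 45 and 316. Splits at 12 and 48 h that call this many, where the real split calls 0, point to a structure of the samples, and same-numbered arrays deviated together. For called gene lists, 8 of 10 splits gave at least the real 3 at 6 h (highest other 8), 1 of 10 the real 8 at 12 h (highest other 7) and 6 of 10 the real 5 at 48 h (highest other 8). At 48 h the real split had the smallest p of the 10 for the pathogenesis-related list (lowest other adjusted p 1.24e-08), the isoflavonoid list (1.89e-04) and the clock (0.0503), while 2 splits gave a p as small for the ribosome and 5 for WRKY factors. At 12 h it had the smallest p for the pathogenesis-related list (0.0448), peroxidases (0.051) and the cell wall (0.164), while 2 splits gave a p as small for photosynthesis, abscisic acid and root or nodule markers, 5 for lipoxygenases and 7 for isoflavonoids. At 6 h it had the smallest for phloem markers (0.00979), while 2 gave a p as small for root or nodule markers and 4 for isoflavonoids. These splits do not keep the pairs. Of the 4 swaps of isolates within pairs, 1, the real one, gave a p as small for each of the 5 called lists at 48 h. It did so at 12 h for the pathogenesis-related, peroxidase, cell wall, abscisic acid and root or nodule lists and at 6 h for phloem markers. For photosynthesis and lipoxygenases at 12 h and for the other lists at 6 h 2 swaps did, and for isoflavonoids at 12 h all 4. With 4 swaps no share under 0.05 can be reached. The other swaps called 0 to 8 lists at 6 h, 2 to 5 at 12 h and 0 to 6 at 48 h.

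Against mock, 1 of 10 splits, the real one, gave as many calls in each contrast tested. With HW94-1 the real counts were 27960, 23762 and 15465 at 6, 12 and 48 h, and the highest other splits called 0, 728 and 36. With TW72-1 they were 27923, 23576 and 14836, against 2, 1 and 770. From 6 to 12 h they were 6545 with HW94-1 and 4838 with TW72-1, against 5 and 3. These splits are too few as well.

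For the F tests, 100 splits were drawn within times. All 100 meet the real counts of 0 for an isolate effect at any time and for the interaction by construction, which decides nothing about chance. The splits called up to 476 and 1934, and counts this far above the real ones again point to a structure of the samples. With the block within each sampling time, 8 of 100 swaps within pairs gave at least the real 7 calls of an isolate effect, with up to 21, so chance cannot be excluded. There are 4 such swaps within a time, too few for a share under 0.05: the real count was 18 at 48 h with a highest other of 1, and 5 at 12 h with a highest other of 0, each reached by 1 of the 4.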

How the results depend on the processing

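The block for replicate number within each sampling time and its forms, the replicate block with an estimated correlation, the filter by control probe sets, left-out arrays in the list tests, adjustment over isolate contrasts alone, the overlaps with mock under another scaling or filter, repeated quantile normalization with the additive block, and left-out mock arrays in the list medians against mock were chosen after the data had been seen. The planned filter with HgAffx or PsAffx probe sets was not run. Over all alternatives, left-out arrays included, counts of calls stayed within 1.5 times or at 0 in 327 cases, moved further in 85, went from 0 to calls in 34 and from calls to 0 in 16. Values of named genes and lists kept their direction and their side of the threshold in 2256 cases, lost a call in 158, gained one in 8 and changed sign in 26. Where nothing else is said, the cause was not tested.

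The counts of 0 for the isolates at 6, 12, 24 and 48 h and in both F tests were the same with replicate number as a block, repeated quantile normalization, these together, array weights, fits of the compared groups alone, the added failed arrays and the filter by control probe sets. With an intensity trend and robust prior, 2 probe sets were called at 48 h. The block within each sampling time called 5 at 12 h, 18 at 48 h, 7 in the F test of an isolate effect and 2 in the interaction. With an intensity trend these were 10, 101, 6 and 2, and with a robust prior too 10, 102, 6 and 2. With each time fitted alone that block called 0 at every time, in a fit with fewer arrays to estimate the spread.

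Of all 67 list calls, mock contrasts included, 0 held with an estimated correlation, so the counts at 6, 12, 24 and 48 h were 0 in place of 3, 8, 2 and 5, and they were 0 at all 4 times with either block and an estimated correlation. With 1 probe set per gene, which tests fewer probe sets, 29 lists were called in all, 3 at 12 h, 1 at 24 h and 3 at 48 h. Beyond the lists given above, this ended the calls of abscisic acid (adjusted p 0.0699), cell wall (0.296) and lipoxygenase genes (0.157) at 12 h and of starvation at 24 h (0.21). The filter by control probe sets called 68 lists and ended the calls of abscisic acid (0.053), lipoxygenases (0.0764) and root or nodule markers (0.174) at 12 h.

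The replicate block called 63 lists in all. In the isolate contrasts it ended the cell wall call at 12 h (0.0552) and called phloem markers at 48 h (median -0.18, adjusted p 0.0434, but 0.747 with an estimated correlation). The block within each sampling time called 5 lists at 6 h, adding starvation (median 0.14, adjusted p 0.0377) and lipoxygenases (-0.11, 0.0377). It added heat shock (0.10, 0.00239) and WRKY factors (0.14, 0.036) at 12 h and ethylene (0.35, 0.0231) at 24 h, none of which held with an estimated correlation (adjusted p 0.554 to 0.868), and ended the calls of peroxidases (0.181) and root or nodule markers (0.0545) at 12 h. Neither block changed another call of a list in the isolate contrasts, and no named gene beyond those given with the block.

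Signs changed in the following lists and genes. The median of root or nodule markers at 6 h was -0.051 when dim probe sets were left out, and the cause was not tested. Signal over background limits what can be said of probe sets not above it: of the signs given here, those of LOX2 are of values not above background, and PR1-1 and HSF-35 were above it with HW94-1 alone, on 1 array each. Array weights gave 0.06 for LOX2, -0.07 for PR1-1 and 0.12 for PRX2 at 12 h. The values of LOX2 and PR1-1 are not read as differences between the isolates, and their signs show no reversal. With arrays left out, the isoflavonoid median ran from -0.013 to 0.39 at 6 h and from -0.076 to 0.73 at 12 h, that of abscisic acid from -0.28 to 0.030 at 12 h and that of heat shock from -0.046 to 0.56 at 24 h. At 6 h SUT1 ran from -0.19 to 1.14, IFR2 from -0.17 to 0.95 and SEO-F3 from 0.00 to 0.79. At 12 h PRX2B ran from -0.077 to 0.21, CYP93A1 from -0.13 to 0.95, PIP1-7 from -0.27 to 0.026, PRX2 from -1.58 to 0.59 and PRX3 from -0.008 to 0.35. For HSF-35 no TW72-1 array was above background at 24 h, so its values are not read as differences and show no reversal. At 24 h HSF-35 ran from -0.019 to 2.06, PDIQ-1A from -0.69 to 0.11, HSF-08 from -0.30 to 1.21 and AS2 from -1.06 to 0.36, and at 48 h LUXC from -1.55 to 0.51 and LCL3 from -0.83 to 0.047. Of these genes, HSF-35 was called without HW94-1 24 h replicate 3, and in all cases fewer arrays were compared.

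With arrays left out, the isolate counts ran from 0 to 1 at 12 h, 0 to 118 at 24 h and 0 to 2 at 48 h, the F test from 0 to 12 and the interaction from 0 to 10. With the block within each sampling time they ran from 0 to 43, 6 to 1337 and 5 to 55 at 12, 24 and 48 h. The arrays behind these counts are named in the report. The list counts ran from 1 to 8 at 6 h (8 without TW72-1 replicate 3, 5 without HW94-1 replicate 3, 6 and 1 without replicate 3 or 1 of both) and from 4 to 10 at 12 h (4 without TW72-1 replicate 2 or replicate 3 of both, 5 without HW94-1 replicate 3 or replicate 1 of both). They ran from 1 to 5 at 24 h (5 without HW94-1 replicate 3 or replicate 2 of both, 4 without HW94-1 replicate 2, 1 without replicate 1 at the other times) and from 3 to 7 at 48 h (3 without HW94-1 replicate 3). Where leaving out an array left 1 at 24 h, that array is assumed to vary like the other groups.

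Counts that cross the separately normalized sets moved too. Repeated quantile normalization gave 7625, 8138 and 7847 calls against mock with HW94-1 at 6, 12 and 24 h, and 8583, 7023, 5113 and 9829 with TW72-1 at 6, 12, 24 and 48 h. It gave 3011 and 4463 from 6 to 12 h and 12 to 24 h with HW94-1, 2052 and 2224 with TW72-1, and 6782, 6147, 4592 and 8083 calls shared by the isolates at 6, 12, 24 and 48 h. Fits of the compared groups alone, with fewer arrays to estimate the spread, gave 9720 for HW94-1 at 48 h and 9385 for TW72-1 at 24 h against mock. Between times they gave 3053, 1985 and 5566 with HW94-1, and with TW72-1 0 from 12 to 24 h and 5014 from 24 to 48 h. From 6 to 12 h array weights gave 14502 and 10627 with HW94-1 and TW72-1, and the replicate block 9947 and 7900. The filter by control probe sets gave 2754 with TW72-1 from 12 to 24 h. With arrays left out, HW94-1 ran from 1431 to 5287, 2348 to 6034 and 5865 to 14031 between successive times, and TW72-1 from 870 to 3469, 518 to 4087 and 5755 to 12218. Single arrays moved these counts by over 1.5 times as follows. From 6 to 12 h HW94-1 had 3792 or 4107 calls without 6 h replicate 1 or 2 and 4046 without 12 h replicate 3, and TW72-1 had 2560, 2770 or 2522 without 6 h replicate 1, 2 or 3 and 2111 without 12 h replicate 3. From 12 to 24 h HW94-1 had 3351 or 3929 without 24 h replicate 2 or 3, and TW72-1 had 2769 without 12 h replicate 3 and 955 without 24 h replicate 3. Without 24 h replicate 3, HW94-1 had 6803 from 24 to 48 h, and TW72-1 had 7884 from 24 to 48 h and 11183 at 24 h against mock. Against mock HW94-1 ran from 8126 to 16658 at 24 h, and TW72-1 from 8157 to 15459 at 24 h and 9877 to 14163 at 48 h.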

Other observations

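Left-out mock arrays were added after the medians had been seen, and the values against mock leaves are those after repeated quantile normalization, given without a test. The genes were chosen after their values were seen. KTI-3, a Kunitz trypsin inhibitor, lay below mock at 12 h and above it at 48 h with both isolates. It was at 6.56 ± 1.18 (SD, n = 3) in mock leaves, at 4.22 ± 0.33 and 4.19 ± 0.36 (n = 3 each) with HW94-1 and TW72-1 at 12 h, and at 9.70 ± 0.99 and 9.57 ± 1.05 (n = 3 each) at 48 h. At 12 h it was above background on 1 of 3 arrays with each isolate. KTI-2 differed from mock by 2.78 and 2.70 at 48 h. In jasmonate synthesis, LOX10 differed by 3.47 and the allene oxide cyclase AOC6 by 2.43 with HW94-1 at 48 h, and AOC3 by 2.11 with each isolate, while the list median was 0.00 with HW94-1 and 0.28 with TW72-1. Without mock replicate 2 these medians were 0.34 and 0.50, and without mock replicate 1 they were -0.03 and 0.16. LOX10 and AOC6 were above background on 2 of 3 mock arrays.

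The flavonol synthase FLS1 was at 9.19 ± 0.95 (SD, n = 3) in mock leaves and differed by -2.18 and -1.72 at 12 h and by 1.94 and 2.10 at 48 h with HW94-1 and TW72-1. The medians of the flavonol and anthocyanin list lay at percentiles of 13.9 and 16.8 of random lists at 12 h and of 78.2 and 82.5 at 48 h. The flavanone hydroxylase F3H, above background on 2 of 3 arrays of each isolate, differed by -4.29 and -4.36 at 12 h. Of the coumarate ligases, 4CL1 differed by -4.10 and -3.88 and 4CL3 by 1.89 and 2.19 at 12 h. Cell wall genes had medians of -0.92 and -0.43 at 12 h, -1.38 and -0.92 at 24 h, and 0.11 and -0.01 at 48 h, and they depended on single mock arrays. With each left out in turn they ran from -2.02 to -0.42 and -1.42 to -0.11 at 12 h, -2.03 to -0.97 and -1.52 to -0.64 at 24 h, and -0.28 to 0.25 and -0.32 to 0.22 at 48 h, each lowest without replicate 3. The glutathione transferase GST3 differed by -3.11 and -2.91 and the catalase CAT1 by -1.16 and -1.29 at 48 h.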
